A study of Homo sapiens with 6 samples.

How the data were processed

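RNA of 3 stable lines of HCT116, an established human colorectal carcinoma cell line, was measured on 6 Agilent 1-colour expression arrays, 2 per line. Per the labels' protocols, the lines were made by retroviral transduction with an empty vector, with an shRNA (a short hairpin RNA that lowers its target transcript) named PHF19L sh1, or with one named PHF19S sh1. The labels give 2 biological replications per line but do not say whether these were separate cultures, so p-values measure the spread between these samples, which may be technical. The labels name the vector of all lines pSuper Retro Neo but give puromycin selection, so the marker used is not clear. Each isoform had 1 shRNA and the series 1 control line. Per the labels' protocols, RNA was isolated on spin columns and labelled with Cy3.

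Per the file headers, the arrays were of Agilent design 014850 and were read with Feature Extraction 10.7.3.1, and the deposited spot intensities are background-corrected processed signals on a linear scale. The authors' value table holds log2 values, which were compared here with the scanner values. Over 41093 matched probes per array, 99.52 to 99.61% of its values lay within 0.01 of log2 of the processed signal with the spots of a probe averaged (r of at least 0.9999), so the table was not scaled between arrays or centred on genes, and with 1 colour it has no direction. Its column medians were 5.46 and 5.67 for vector, 5.96 and 6.10 for PHF19L sh1, and 6.09 and 6.15 for PHF19S sh1. How the authors compared the groups is not given in the sources used here. Probe positions in the files are on hg19, and no genome was used.

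Each array carried 45015 spots, of which 43376 held the 41000 probes that are not controls, and 264 of these probes were printed on 10 spots each. Control spots and the 40 to 97 spots per array marked as outliers by the scanner software were left out, and replicate spots were averaged. Signals were taken as log2 of the processed signal minus the array's 75th percentile of it. A probe was tested when it lay well above background, by the scanner software's own mark, on both arrays of at least 1 group. A gene was represented by its brightest tested probe over the 6 arrays, which left 20218 genes, and every PHF19 probe was also tested separately among the 28626 probes. The files' gene names are those of the array design. Of the 41000 probes, 27294 were renamed through their RefSeq accession, 2383 carried a current symbol, 454 were updated from an older symbol and 10869 kept the name in the file.

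Differences between lines were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 fit over the 3 groups, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. Every adjusted p of a gene is from this fit. It had 3 residual degrees of freedom and 5.54 in all after moderation, and the median replicate SD was 0.087 on the log2 scale. Array intensities have no counting depth, and it is the number of arrays that limits the precision. The 31 gene lists (Polycomb complexes and their targets, cell cycle, stress, signalling, differentiation, metabolism, RNA quality and other cell types) were tested with limma's camera at a preset correlation of 0.01, with camera at the correlation estimated from the data, and with fry, adjusted over the 31 lists. The main adjusted p of a list is the preset one. Fry tests whether the members of a list move, on balance, 1 way and does not compare them with other genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

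The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, all PHF19 probes, the 8 largest increases and the 8 largest decreases among genes that passed the test with groups that did not overlap, up to 4 members of smallest adjusted p from each described list, and, for both lines, the 6 largest changes in the same direction and up to 6 in opposite directions. Many genes it took lay near background in 1 of the groups compared, so genes measured in both groups were also ranked, a choice made after their values were seen. For a gene not well above background on any array of a group only a bound is given ("at least N-fold"): the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal of any probe well above background. Log2 changes of such genes are given only under normexp background correction, for their sign, where it reversed them. For a gene well above background on 1 of 2 arrays of the dimmer group no size is given.

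All vector and PHF19L sh1 arrays lay on slide 1 and in scan 1, and the PHF19S sh1 arrays on slide 2 and in scan 2. The comparison of PHF19L sh1 with vector is therefore within 1 slide, and in each comparison of PHF19S sh1 the slide and the group cannot be told apart. Comparisons with the same 2 vector arrays share their chance values. Overlap and correlation were therefore set beside 50 simulations of unchanged groups against those controls and beside the number expected of independent lists. The 2 controls were not split between the lines, so part of any excess may come from the shared controls.

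The steps were tested on simulated data made from the arrays' own levels and spread, in which 200 of 20218 genes were changed and the 15 genes of 1 list were shifted by 0.5. For PHF19L sh1 against vector, 19.4% of the 67 genes changed by 0.5 on the log2 scale, 86.6% of the 67 changed by 1 and 98.5% of the 66 changed by 2 were recovered, and 12 of the 20003 genes outside these were called. For PHF19S sh1 the shares were 34.3%, 85.1% and 100%, with 7 of the other genes called. The shifted list was called (adjusted p = 2.8e-24 and 1.7e-23, and adjusted p = 0.047 and 0.049 with an estimated correlation), with 0 other lists called. In the data a far larger share of genes was called (46.6% and 56.1%), so the recovered shares may differ there. Simulated genes varied independently on normalized values, so neither correlation between genes nor the normalization was tested. Even so the shifted list barely passed with an estimated correlation. With so few arrays, failing that version of the test is weak evidence against a list.

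Alternatives tried were normexp background correction of the mean and background signals with an offset of 50, quantile normalization, the 75th percentile over probes well above background on all arrays, the authors' value table, no filter on dim probes, only probes well above background on all arrays, outlier spots kept, the mean of a gene's probes or every probe on its own, only the groups compared, a trended and robust prior, a 2-fold threshold, the replicate number as a block, the slide as a block where it could be fitted, and each array left out.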

Results

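Gene expression was measured in 3 stable lines of HCT116, a human colorectal carcinoma cell line. The lines carried an empty retroviral vector, an shRNA directed at the long isoform of PHF19 (PHF19L sh1) or an shRNA directed at the short isoform (PHF19S sh1). PHF19 is a Polycomb-like protein that associates with Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates histone H3 at lysine 27. The series asks how PHF19 isoforms alter gene expression in colon cancer cells. Each line was measured on 2 arrays (n = 2 per group throughout). The 75th percentile of signal was 424.6 and 486.9 on the vector arrays, 570.5 and 625.2 on the PHF19L sh1 arrays and 632.7 and 653.9 on the PHF19S sh1 arrays, and 67.3 to 71.4% of spots lay well above background. Replicates correlated across genes at 0.9978 (vector), 0.9967 (PHF19L sh1) and 0.9971 (PHF19S sh1), against 0.9744 to 0.9889 between arrays of different groups, and no replicate pair held identical values.

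PHF19 itself was measured by 2 probes, 1 for each of 2 RefSeq transcript variants, on chromosome 9 (hg19). The files do not state which variant encodes which isoform. The variant 1 probe (123618245 to 123618304) read −0.66 and −0.65 in vector, −1.58 and −1.73 in PHF19L sh1 and −0.88 and −0.76 in PHF19S sh1, as log2 signal relative to the array's 75th percentile. It fell by 1.0 in PHF19L sh1 (SE 0.09, adjusted p = 0.00081), to 50% of the vector level, while in PHF19S sh1 the change of −0.16 (SE 0.09) did not pass (adjusted p = 0.158, 95% interval −0.37 to 0.05). The variant 2 probe (123631999 to 123632058) read 2.45 and 2.61 in vector, 2.49 and 2.45 in PHF19L sh1 and 2.07 and 2.11 in PHF19S sh1. It fell by 0.44 in PHF19S sh1 (SE 0.08, adjusted p = 0.00558), to 73.7% of the vector level. In comparisons of PHF19S sh1 the slide and the line cannot be told apart. Genes called there against vector had a median absolute log2 change of 0.56. The change of the variant 2 probe in PHF19L sh1 was −0.07 (SE 0.08, adjusted p = 0.529, interval −0.26 to 0.13). This was 0.07 with normexp background correction and 0.01 without vector replicate 2. The difference between the lines, PHF19S sh1 minus PHF19L sh1, was 0.84 on the variant 1 probe (adjusted p = 0.00551) and −0.37 on the variant 2 probe (adjusted p = 0.0258). The latter did not pass without PHF19L sh1 replicate 1 (adjusted p = 0.102), PHF19L sh1 replicate 2 (0.0721), PHF19S sh1 replicate 1 (0.0985) or PHF19S sh1 replicate 2 (0.0851), nor without the filter on dim probes (0.0771).

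**Figure D1:**
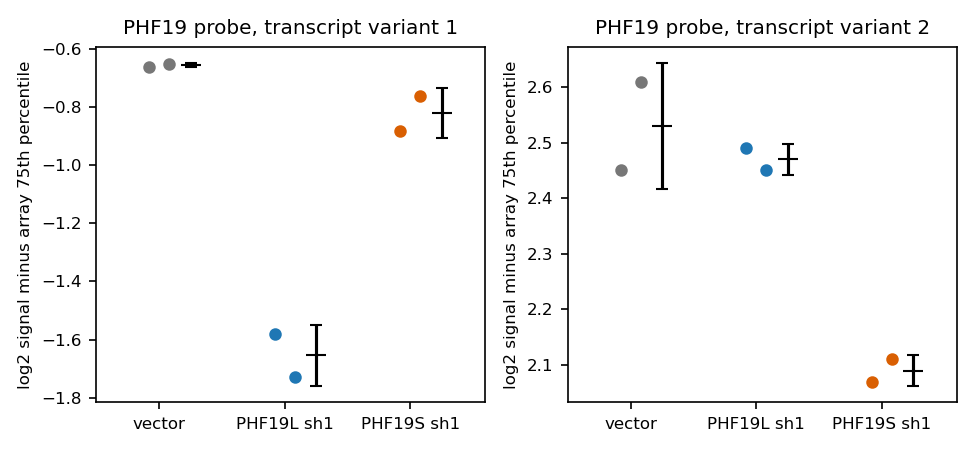
Log2 signal of the PHF19 variant 1 and variant 2 probes relative to the 75th percentile of each array, with a point per array and the mean and SD of each group beside them (n = 2). The variant 1 probe was lowest in PHF19L sh1 (mean −1.66) and the variant 2 probe lowest in PHF19S sh1 (mean 2.09).

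In PHF19L sh1 cells the largest increase over vector was that of DDIT3, a transcription factor of the integrated stress response, which rose 50.4-fold (log2 change 5.66, SE 0.08, adjusted p = 5.3e-05). HERPUD1, an endoplasmic reticulum protein of the degradation pathway for misfolded proteins, rose by 3.19 on the log2 scale (SE 0.08) and the glucose transporter gene SLC2A3 by 3.23 (SE 0.06). The muscle ankyrin repeat gene ANKRD1 rose by 3.59 (SE 0.08), the interleukin 21 receptor gene IL21R by 3.53 (SE 0.09) and the keratin gene KRT86 by 3.40 (SE 0.06). SLC2A3 and KRT86 have near-identical paralogs that their probes may share. CALCA, which encodes calcitonin and its related peptide, rose (adjusted p = 0.0013) from a vector level measured on 1 of 2 arrays, and the neuropeptide gene SPX was at least 7.1-fold higher. The largest decreases measured in both groups were those of the methionyl-tRNA synthetase gene MARS1 (−2.50, SE 0.08), the adenosine receptor gene ADORA1 (−2.23, SE 0.21), the opsin gene OPN1LW (−2.12, SE 0.10) and the Nogo receptor family gene RTN4RL1 (−2.12, SE 0.07). The fall of MARS1 was on 1 of its 2 probes, and the other changed by −0.14. IL10 fell (adjusted p = 0.00038) to a level measured on 1 of 2 arrays, and TMEM108 was at least 4.1-fold and SPATA31A1 at least 1.4-fold lower. HOXD9 fell (adjusted p = 0.044) to a level measured on 1 of 2 arrays. HOXD9 did not pass without vector replicate 1 (adjusted p = 0.155), vector replicate 2 (0.153), PHF19S sh1 replicate 1 (0.0666) or PHF19S sh1 replicate 2 (0.0706), nor did SPATA31A1 without vector replicate 2 (0.0644) or PHF19L sh1 replicate 2 (0.0572). HOXD9 was also not called without the filter on dim probes (adjusted p = 0.107), with only the groups compared (0.0561) or with the trended prior (0.128). With normexp background correction SPX was no longer called (adjusted p = 0.649).

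Of 20218 genes tested, 9421 (46.6%) differed between PHF19L sh1 and vector, 4593 higher and 4828 lower, with a median absolute log2 change of 0.51. The groups of 15533 genes (76.8%) did not overlap, against 33.3% by chance for 2 arrays against 2. At least 2-fold changes were seen for 1127 genes, 845 higher and 282 lower, or 643 higher and 212 lower among the 18917 genes measured in both groups. Normexp background correction with its offset moved the median of all genes from −0.035 to −0.229 and the split of calls to 1855 higher and 7177 lower (20.5% higher against 48.8%). Directions here are relative to the 75th percentile of each array, and in each comparison with vector that correction turned called members of several gene lists, not all of which are named. The count was 5864 without vector replicate 1 and 5838 without vector replicate 2.

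Genes of the unfolded protein and ATF4 response rose together in PHF19L sh1. Of 28 measured members 26 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 change of 1.71. Beside DDIT3 and HERPUD1 these included HSPA5, the main chaperone of the endoplasmic reticulum (2.80, SE 0.06), and the pseudokinase gene TRIB3 (2.51, SE 0.06). The list passed camera at adjusted p = 1.26e-17, and at adjusted p = 0.064 with an estimated correlation it did not. MAPK and immediate-early genes had 22 of 32 members higher and 3 lower (23 and 3 adjusted over the list alone, median 0.73). These included JUN (2.08, SE 0.06), the phosphatase gene DUSP5 (2.0, SE 0.07), EGR3 (2.24, SE 0.09) and ATF3 (3.09, SE 0.16). ATF3 is also a member of the unfolded protein list. The MAPK list had adjusted p = 1.55e-07, and adjusted p = 0.067 with an estimated correlation. Of 21 hypoxia-induced genes 17 rose and 0 fell (18 and 1 adjusted over the list alone, median 0.69). These included VEGFA, the endothelial growth factor (1.61, SE 0.08), ANKRD37 (2.04, SE 0.07) and the hexokinase gene HK2 (1.45, SE 0.07). The test gave adjusted p = 1.82e-07, and adjusted p = 0.067 with an estimated correlation.

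Smaller shifts upward were found for p53 targets, inflammatory genes, interferon-stimulated genes and epithelial adhesion genes. Of 30 p53 target genes 15 rose and 4 fell (15 and 4 adjusted over the list alone, median 0.32). First among them were SESN2 (2.04, SE 0.08), GADD45A (1.30, SE 0.07) and GDF15 (1.30, SE 0.07). This list had adjusted p = 0.00963, and adjusted p = 0.17 with an estimated correlation. SESN2 is also on the unfolded protein list. Of 18 NF-kB and inflammatory genes 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.45). These included the apoptosis inhibitor BIRC3 (1.59, SE 0.08) and the chemokines CXCL2 (1.14, SE 0.08, adjusted p = 0.31 with normexp) and CXCL8 (at least 2.2-fold higher, but −0.54 with normexp background correction). The list had adjusted p = 0.00183 (adjusted p = 0.14 with an estimated correlation), and with normexp a median of 0.07 and adjusted p = 0.0558. Interferon-stimulated genes had 17 of 28 higher and 3 lower (18 and 4 adjusted over the list alone, median 0.30). These included the RNA sensor RIGI (1.16, SE 0.07), ISG20 (1.08, SE 0.07), OASL (1.09, SE 0.07) and IFIT2 (1.23, SE 0.08). For the list camera gave adjusted p = 0.00183 (adjusted p = 0.14 with an estimated correlation). With normexp the median was 0.09, and IFIT3, MX1 and TRIM22 turned from higher to lower. Of 24 epithelial adhesion genes 11 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.21). First among them were the laminin gene LAMB3 (2.16, SE 0.07) and the splicing factor gene ESRP1 (2.29, SE 0.11). The E-cadherin gene CDH1 rose by 0.74 (SE 0.06). That list had adjusted p = 0.0303 (adjusted p = 0.41 with an estimated correlation). Without PHF19L sh1 replicate 2 it had adjusted p = 0.0659.

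E2F and DNA replication genes fell in PHF19L sh1: 0 of 39 rose and 25 fell (0 and 27 adjusted over the list alone), with a median of −0.49. CDC25A, a phosphatase that activates cyclin-dependent kinases, changed by −0.97 (SE 0.06), the replicative helicase gene MCM2 by −0.86 (SE 0.06), GINS1 by −0.98 (SE 0.07) and E2F2 by −0.98 (SE 0.08). The list had adjusted p = 1.82e-07 (adjusted p = 0.067 with an estimated correlation). Mitosis genes were mixed, with 15 of 37 lower and 5 higher (the same numbers adjusted over the list alone, median −0.17). MKI67 changed by −1.01 (SE 0.08) and BIRC5 by −0.66 (SE 0.06), whereas ASPM rose by 0.86 (SE 0.07) and the kinetochore motor gene CENPE by 0.74 (SE 0.06). They had adjusted p = 0.00931 (adjusted p = 0.19 with an estimated correlation), and with normexp the direction of the test turned at a median of −0.14 (adjusted p = 0.613). Of 15 heat shock genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median −0.52). HSPA1A was at −1.68 (SE 0.09), HSPA8 at −0.96 (SE 0.11) and DNAJB4 at 0.84 (SE 0.10, adjusted p = 0.236 with normexp). This list had adjusted p = 0.00434 (adjusted p = 0.16 with an estimated correlation). With normexp it had adjusted p = 0.0825.

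Because PHF19 acts with PRC2, lists of Polycomb subunits and targets were included. The adjusted p of each list below is that of camera. Fry also passed PRC2 subunits (adjusted p = 0.016, downward), HOX genes (0.0029, downward), PRC1 subunits (0.0029, upward) and CDK inhibitors (0.047, upward) in PHF19L sh1. Developmental regulators bound by Polycomb fell more often than they rose in PHF19L sh1: 29 of 62 measured members were lower and 2 higher (29 and 2 adjusted over the list alone, median −0.35). These included FOXC1 (−1.15, SE 0.07), ISL1 (−0.91, SE 0.07), LHX2 (−0.74, SE 0.07) and SOX2 (−0.71, SE 0.07). That list had adjusted p = 0.000226 (adjusted p = 0.14 with an estimated correlation). Of 11 PRC2 subunit genes 0 rose and 3 fell (0 and 2 adjusted over the list alone, median −0.19, adjusted p = 0.365). These were EED (−0.45, SE 0.06), RBBP7 (−0.36, SE 0.08) and JARID2 (−0.25, SE 0.08). EED (adjusted p = 0.0747), RBBP7 (0.312) and JARID2 (0.171) were not called with normexp, and RBBP7 not without vector replicate 1 (adjusted p = 0.0841), vector replicate 2 (0.0535) or PHF19L sh1 replicate 1 (0.055). JARID2 was not called without vector replicate 1 (0.0908), vector replicate 2 (0.2), PHF19L sh1 replicate 2 (0.144), PHF19S sh1 replicate 1 (0.0735) or PHF19S sh1 replicate 2 (0.0759). HOX genes, classical Polycomb targets, had 5 of 30 higher and 12 lower (6 and 14 adjusted over the list alone, median −0.18, adjusted p = 0.217). Of these HOXB9 (1.14, SE 0.06) and HOXB2 (1.05, SE 0.07) were higher and HOXA13 (−0.65, SE 0.07) and HOXA10 (−0.63, SE 0.07) lower. PRC1 subunits had 8 of 17 higher and 4 lower (8 and 4 adjusted over the list alone, median 0.28, adjusted p = 0.217). Among 7 CDK inhibitors 3 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.04, adjusted p = 0.747). CDKN1A was at 0.63 (SE 0.06), CDKN2B at 0.85 (SE 0.07, not called with normexp, adjusted p = 0.595), CDKN2C at −0.88 (SE 0.08) and CDKN2D at −0.56 (SE 0.08).

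The other lists did not pass camera in PHF19L sh1, and the adjusted p given for each is that of camera. By fry, which does not compare members with other genes, all of them but the intestinal, glycolysis, cancer-testis and leukocyte lists passed. Mesenchymal transition genes, for example, had a fry adjusted p = 8.7e-05, and markers of the HEK293 type 4e-04. Members higher and lower numbered 5 and 9 of 19 Wnt and beta-catenin target genes (median −0.21, adjusted p = 0.315), 2 and 2 of 12 intestinal differentiation genes (median −0.17, adjusted p = 0.929, fry upward) and 6 and 2 of 17 mesenchymal transition genes (median 0.09, adjusted p = 0.134). Protease, growth factor and metabolic lists gave 6 and 3 of 14 matrix-degrading protease genes (median 0.17, adjusted p = 0.297) and 8 and 6 of 18 TGF-beta target genes (median 0.25, adjusted p = 0.309), and 3 and 6 of 18 glycolysis genes (median −0.07, adjusted p = 0.542). They numbered 11 and 5 of 24 cholesterol synthesis genes (median 0.20, adjusted p = 0.0953), 8 and 6 of 20 NRF2 antioxidant genes (median −0.11, mean 0.05 and test upward, adjusted p = 0.929) and 4 and 3 of 14 cancer-testis genes (median 0.04, adjusted p = 0.774). For quality, they numbered 0 and 5 of 49 ribosomal protein genes (0 and 0 adjusted over the list alone, median −0.11, adjusted p = 0.0574) and 1 and 10 of 35 respiratory chain genes (median −0.16, adjusted p = 0.0556). Reference genes gave 1 and 4 of 15 (median −0.06, adjusted p = 0.318), of which TFRC changed by −0.74 and PPIA by −0.41. Markers of other cell types gave 1 and 0 of 2 for fibroblasts (median 0.28, adjusted p = 0.22) and 0 and 2 of 10 for leukocytes (median −0.18, adjusted p = 0.562). They gave 0 and 2 of 4 for endothelium (median −0.07, adjusted p = 0.607) and 0 and 2 of 6 for the HEK293 type of packaging cell (median −0.30, adjusted p = 0.365). Adjusted over the list alone the higher and lower numbers were 6 and 9 for Wnt, 9 and 6 for TGF-beta, 13 and 5 for cholesterol synthesis and 1 and 9 for respiratory chain genes. For the remaining lists of these groups they were those over all genes. With normexp the medians turned for mesenchymal transition (−0.16), protease (−0.04), TGF-beta (−0.31), glycolysis (0.07), NRF2 (0.02), cancer-testis (−0.34) and fibroblast genes (−0.20), and quantile normalization turned those of glycolysis (0.05), cancer-testis (−0.02) and ribosomal protein genes (0.04).

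**Figure D2:**
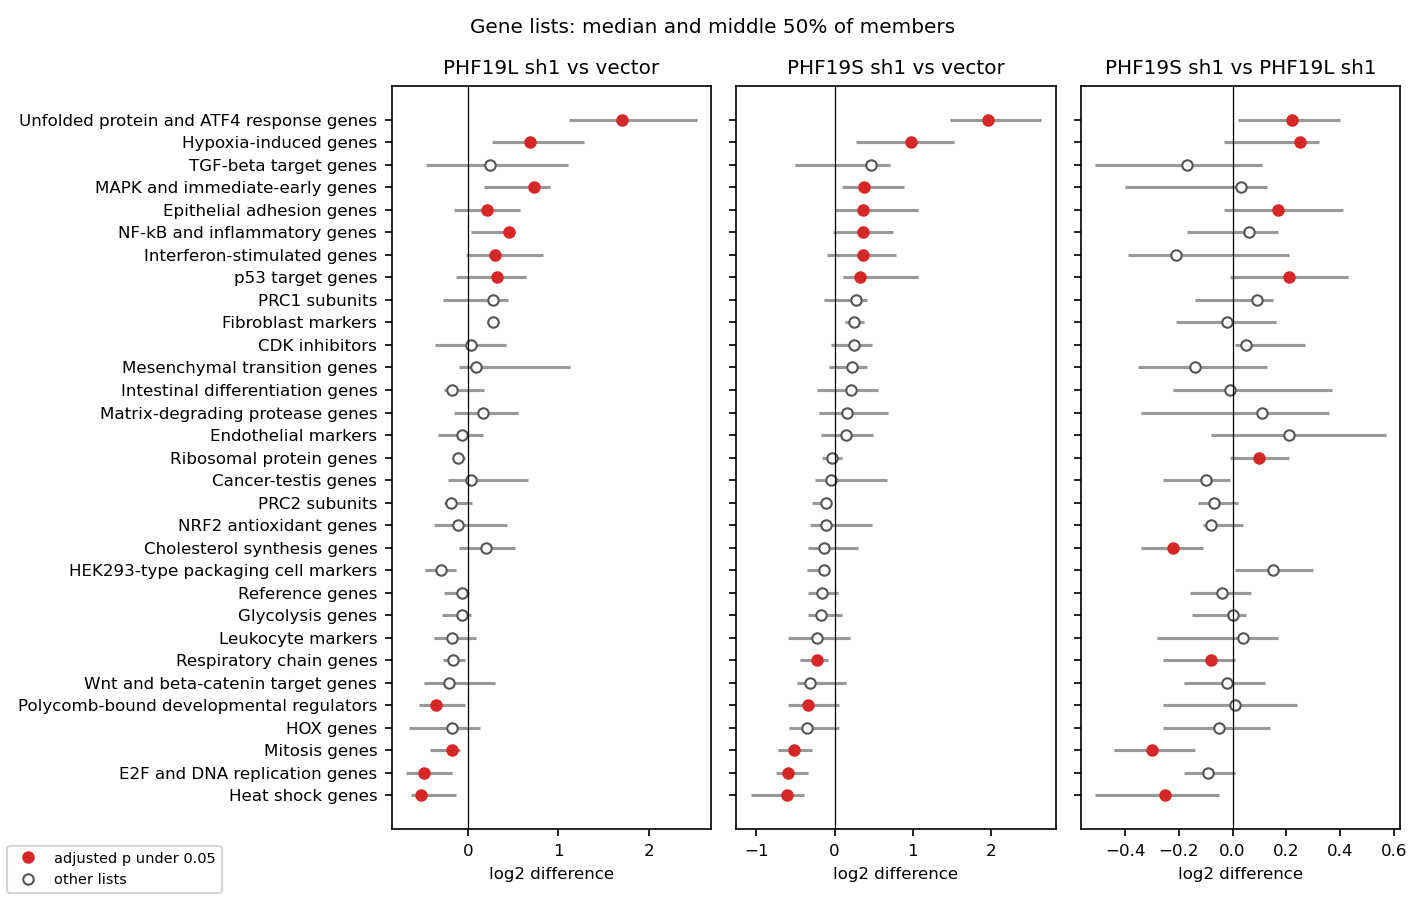
Median log2 difference of each gene list (circles) and the middle 50% of its members (lines) in the 3 comparisons, with filled circles for adjusted p under 0.05 in camera at the preset correlation of 0.01. Unfolded protein and ATF4 response genes lay farthest to the right against vector in both knockdown lines (1.71 and 1.96), and some medians turned direction with normexp background correction, among them that of TGF-beta target genes in PHF19S sh1 (0.47 to −0.36).

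In PHF19S sh1 cells DDIT3 rose 41.3-fold over vector (log2 change 5.37, SE 0.08, adjusted p = 2.5e-05) and the interleukin 20 receptor gene IL20RB 23.0-fold (4.53, SE 0.07). SPX was at least 27-fold higher, and KLHDC7B rose (adjusted p = 0.00039) from a vector level measured on 1 of 2 arrays. The next largest increases included genes not well above background in vector, namely NSG1 (at least 5.9-fold), MYO1H (at least 5.3-fold), AQP4 (at least 4.3-fold) and XDH (at least 6.4-fold). The 8 largest decreases were all of genes not well above background in PHF19S sh1, namely HOXD9 (at least 11-fold), KLF17 (8.5-fold), NPTX2 (7.3-fold), APOC2 (4.6-fold), PTPRO (3.2-fold), IBSP (3.0-fold), ANGPTL8 (4.3-fold) and EDDM3A (3.1-fold), each a lower bound. NSG1, MYO1H, AQP4, XDH and these decreases other than HOXD9 and PTPRO lay 8-fold or more from both other groups on the PHF19S sh1 arrays alone and had 0 other tested probes, so an artefact of that slide was not excluded for them. Among genes measured in both groups, a ranking chosen after the values were seen, IL21R rose by 3.97 (SE 0.09), LURAP1L by 3.97 (SE 0.15), the hexokinase-like gene HKDC1 by 3.80 (SE 0.06), KRT86 by 3.63 (SE 0.06) and the fucosyltransferase gene FUT3 by 3.62 (SE 0.08). In the same ranking LKAAEAR1 changed by −2.84 (SE 0.23), ADORA1 by −2.40 (SE 0.21), MARS1 by −2.30 (SE 0.08), RTN4RL1 by −2.19 (SE 0.07) and THEM6 by −2.09 (SE 0.08). The other MARS1 probe changed by 0.01. With normexp background correction AQP4 turned to −0.10, and NSG1 (adjusted p = 0.879), MYO1H (0.812) and XDH (0.563) were not called. HOXD9 was not called without vector replicate 1 (adjusted p = 0.0788), vector replicate 2 (0.079), PHF19S sh1 replicate 1 (0.0609) or PHF19S sh1 replicate 2 (0.0587), nor with the trended prior (0.0669). NSG1 was not called without vector replicate 2 (adjusted p = 0.0531), APOC2 not without vector replicate 2 (0.0579) or PHF19S sh1 replicate 1 (0.0503), and MYO1H not without PHF19S sh1 replicate 2 (0.139) or the filter on dim probes (0.116).

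Between PHF19S sh1 and vector 11344 genes (56.1%) differed, 5329 higher and 6015 lower, with a median absolute log2 change of 0.56 and groups that did not overlap for 81.5% of genes (33.3% by chance). At least 2-fold changes numbered 1172 higher and 815 lower, or 851 higher and 460 lower among the 18493 genes measured in both groups. The normexp correction moved the median of all genes from −0.034 to −0.259 and the calls to 2717 higher and 8360 lower (24.5% higher against 47.0%). All PHF19S sh1 arrays lay on a slide of their own, so the slide and the line cannot be told apart here.

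Unfolded protein and ATF4 response genes were the most shifted list in PHF19S sh1 also. All 28 measured members rose (28 and 0 adjusted over the list alone, median 1.96). These included HSPA5 (3.04, SE 0.06), TRIB3 (2.75, SE 0.06) and the glutathione-degrading enzyme gene CHAC1 (2.78, SE 0.07). This list had adjusted p = 8.71e-17, and adjusted p = 0.069 with an estimated correlation. Of 21 hypoxia-induced genes 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.97). These included SLC2A3 (3.52, SE 0.06), VEGFA (2.01, SE 0.08), ANKRD37 (1.97, SE 0.07) and the collagen prolyl hydroxylase gene P4HA1 (1.53, SE 0.07). This gave adjusted p = 1.19e-07 (adjusted p = 0.082 with an estimated correlation). MAPK and immediate-early genes had 20 of 32 higher and 3 lower (20 and 3 adjusted over the list alone, median 0.37). JUN was at 2.12 (SE 0.06), DUSP5 at 2.14 (SE 0.07), ATF3 at 3.35 (SE 0.16) and DUSP2 at −1.21 (SE 0.06). This gave adjusted p = 6.86e-05 (adjusted p = 0.094 with an estimated correlation). Of 30 p53 target genes 18 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.33). First among them were GADD45A (1.82, SE 0.07), SESN2 (2.07, SE 0.08), GDF15 (1.74, SE 0.07) and the decoy receptor gene TNFRSF10C (1.55, SE 0.08). For the list camera gave adjusted p = 0.000187 (adjusted p = 0.11 with an estimated correlation). Epithelial adhesion genes had 14 of 24 higher and 4 lower (14 and 4 adjusted over the list alone, median 0.36). These included LAMB3 (2.73, SE 0.07), CDH1 (1.47, SE 0.06), ESRP1 (2.47, SE 0.11) and the tight junction gene OCLN (1.19, SE 0.06). Camera gave adjusted p = 0.00386 (adjusted p = 0.35 with an estimated correlation).

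Of 18 NF-kB and inflammatory genes 10 rose and 2 fell in PHF19S sh1 (10 and 2 adjusted over the list alone, median 0.36). CXCL2 rose by 1.58 (SE 0.08), BIRC3 by 0.94 (SE 0.08) and CXCL8 was at least 2.6-fold higher, with CXCL8 at −0.46 under normexp background correction. The list had adjusted p = 0.0153 (adjusted p = 0.20 with an estimated correlation). With normexp it had a median of 0.06 and adjusted p = 0.0722. Interferon-stimulated genes had 14 of 28 higher and 5 lower (14 and 6 adjusted over the list alone, median 0.36). ISG20 was at 1.97 (SE 0.07), OASL at 0.86 (SE 0.07), IRF7 at 0.87 (SE 0.07) and OAS3 at −0.87 (SE 0.06). For the list camera gave adjusted p = 0.0428 (adjusted p = 0.23 with an estimated correlation). That call was lost without PHF19L sh1 replicate 1 (adjusted p = 0.0684), without PHF19L sh1 replicate 2 (0.0518), with normexp (0.07, at a median of 0.01 and with IFIT3, MX1, BST2, DDX60 and TRIM22 turned), without the filter on dim probes (0.0821), with only probes well above background on all arrays (0.0632) and with only the groups compared (0.0723).

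Cell cycle genes fell in PHF19S sh1. Of 39 E2F and DNA replication genes 0 rose and 33 fell (0 and 33 adjusted over the list alone, median −0.59). These included CDC25A (−0.99, SE 0.06), MCM2 (−0.92, SE 0.06), POLA2 (−0.96, SE 0.07) and ORC1 (−0.95, SE 0.07). Of 37 mitosis genes 0 rose and 28 fell (0 and 31 adjusted over the list alone, median −0.52). These included BIRC5 (−1.10, SE 0.06), the cyclin gene CCNB1 (−1.08, SE 0.07), KIF20A (−0.87, SE 0.06) and the spindle checkpoint kinase gene BUB1B (−0.90, SE 0.06). Each of the 2 lists had adjusted p = 4.56e-08 (adjusted p = 0.082 with an estimated correlation). Heat shock genes had 11 of 15 lower and 1 higher (12 and 1 adjusted over the list alone, median −0.61). HSPA1A was at −1.71 (SE 0.09), HSPE1 at −1.32 (SE 0.08), HSP90AA1 at −0.95 (SE 0.06) and DNAJA1 at −1.12 (SE 0.07). Camera gave adjusted p = 0.000653 (adjusted p = 0.12 with an estimated correlation). Respiratory chain genes had 15 of 35 lower and 0 higher (13 and 0 adjusted over the list alone, median −0.22). NDUFA2 was at −0.85 (SE 0.07), CYC1 at −0.83 (SE 0.07) and NDUFB3 at −0.74 (SE 0.07). The test gave adjusted p = 0.00386 (adjusted p = 0.27 with an estimated correlation). With normexp it had adjusted p = 0.968.

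Of 62 developmental regulators bound by Polycomb 34 fell and 6 rose in PHF19S sh1 (37 and 7 adjusted over the list alone, median −0.34, adjusted p = 0.00728, and adjusted p = 0.19 with an estimated correlation). FOXC1 changed by −1.32 (SE 0.07) and ISL1 by −1.11 (SE 0.07), SOX2 was at least 2.2-fold lower, and BARX1 was at least 1.5-fold higher but at −0.50 with normexp background correction. Among 11 PRC2 subunit genes 0 rose and 5 fell (0 and 4 adjusted over the list alone, median −0.11, adjusted p = 0.211), EED by the most in relation to its error (−0.51, SE 0.06). Of these EPOP, RBBP7 and RBBP4 each lost the call when a single array was left out. RBBP7 was also not called with normexp, nor RBBP4 without the filter on dim probes. HOX genes had 4 of 30 higher and 15 lower (4 and 16 adjusted over the list alone, median −0.35, adjusted p = 0.0985). Of these HOXB9 (1.75, SE 0.06) and HOXB2 (0.93, SE 0.07) were higher and HOXA7 (−1.19, SE 0.12) and HOXA10 (−0.70, SE 0.07) lower. PRC1 subunits had 8 of 17 higher and 2 lower (8 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.208). CDK inhibitors had 4 of 7 higher and 2 lower (5 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.312). Of the called members CDKN2B was not called with normexp. CDKN2A was not called with the mean of its probes, and it lost the call when a single array was left out. CDKN1A was at 0.64 (SE 0.06) and CDKN2C at −1.09 (SE 0.08). Fry, unlike camera, passed PRC2 subunits (adjusted p = 0.0065, downward), HOX genes (0.0018, downward), PRC1 subunits (0.0017, upward) and CDK inhibitors (0.0083, upward).

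The remaining lists did not pass camera in PHF19S sh1, and the adjusted p given for each is that of camera. By fry the Wnt, mesenchymal transition, protease, glycolysis, reference, fibroblast and HEK293 lists passed and the others did not. Mesenchymal transition genes, for example, had a fry adjusted p = 0.00017, and TGF-beta target genes 0.26. Members higher and lower numbered 4 and 10 of 19 Wnt and beta-catenin target genes (median −0.31, adjusted p = 0.273), 3 and 3 of 12 intestinal differentiation genes (median 0.21, mean −0.03 and test upward, adjusted p = 0.561) and 6 and 3 of 17 mesenchymal transition genes (median 0.22, adjusted p = 0.208). They were 7 and 4 of 14 matrix-degrading protease genes (median 0.16, adjusted p = 0.325) and 9 and 8 of 18 TGF-beta target genes (median 0.47, adjusted p = 0.573), and 3 and 9 of 18 glycolysis genes (median −0.17, adjusted p = 0.384). Cholesterol synthesis and the further lists gave 7 and 7 of 24 cholesterol synthesis genes (7 and 9 adjusted over the list alone, median −0.13, mean 0.02 and camera downward, adjusted p = 0.843) and 7 and 7 of 20 NRF2 antioxidant genes (median −0.11, mean 0.02 and camera downward, adjusted p = 0.886). They were 4 and 3 of 14 cancer-testis genes (median −0.04, mean 0.25 and camera upward, adjusted p = 0.943). Ribosomal protein genes gave 6 and 4 of 49 (0 and 0 adjusted over the list alone, median −0.03, adjusted p = 0.994) and reference genes 2 and 7 of 15 (median −0.16, adjusted p = 0.273). Markers gave 1 and 0 of 2 for fibroblasts (median 0.25, adjusted p = 0.429) and 1 and 4 of 10 for leukocytes (median −0.22, adjusted p = 0.561). Those of endothelium gave 1 and 1 of 4 (0 and 1 adjusted over the list alone, median 0.15, fry downward, adjusted p = 0.768), and 0 and 1 of 6 were found for the HEK293 type of packaging cell (0 and 0 adjusted over the list alone, median −0.14, adjusted p = 0.561). Where not given, the numbers adjusted over the list alone were those over all genes. With normexp the medians turned for intestinal (−0.57), protease (−0.17), TGF-beta (−0.36), ribosomal protein (0.12), fibroblast (−0.28) and endothelial genes (−0.48), and with quantile normalization that of ribosomal protein genes (0.09).

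**Figure D3:**
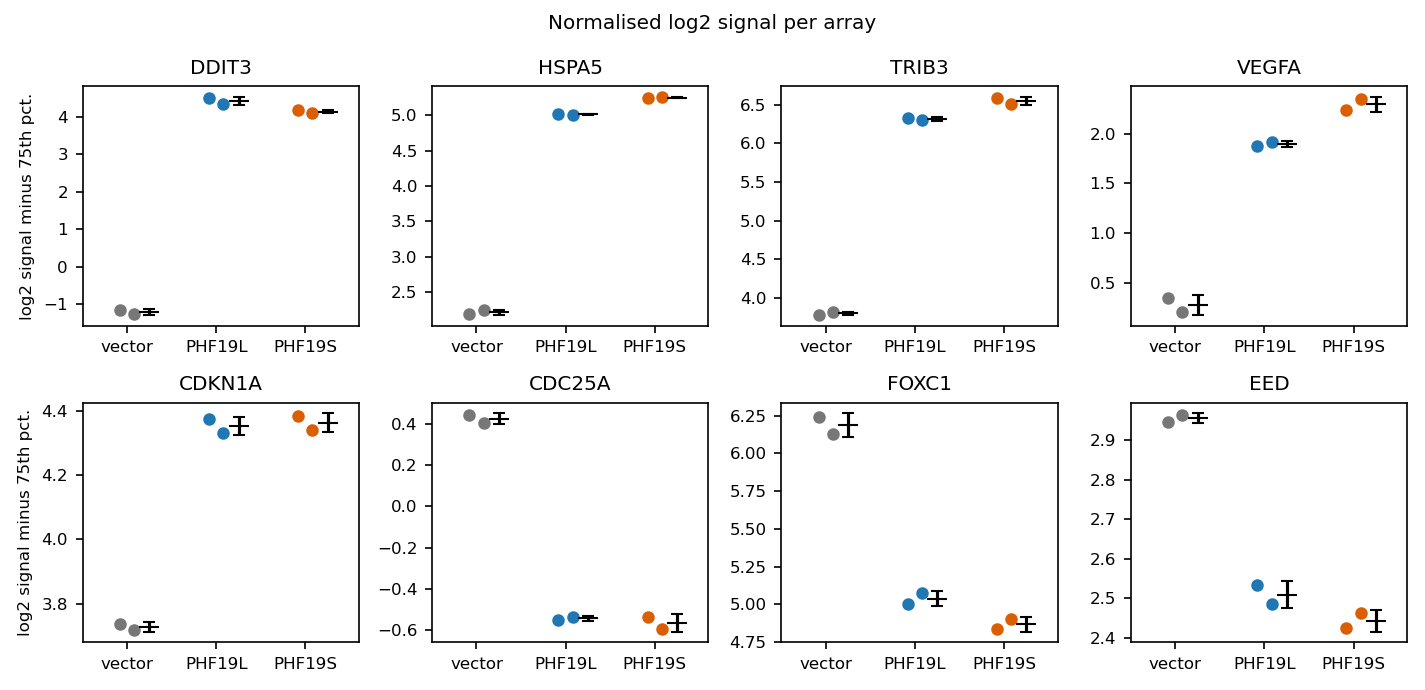
Log2 signal relative to the 75th percentile of each array for DDIT3, HSPA5, TRIB3, VEGFA, CDKN1A, CDC25A, FOXC1 and EED, with a point per array and the mean and SD of each group beside them (n = 2, axes differ between genes and do not start at 0). DDIT3 read −1.22 in vector against 4.43 in PHF19L sh1 and 4.15 in PHF19S sh1 on average, and FOXC1 6.19 against 5.04 and 4.87.

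Most genes that changed in both lines changed in the same direction. Against vector 3552 genes rose in both lines and 3720 fell in both, and 143 moved in opposite directions. Independent lists would share 1211, 1436 and 2639. Simulated unchanged groups, with every array drawn as noise, gave medians of 0, 0 and 0, because few genes are called where none is changed. The simulated values show what noise with a shared control group gives, not what lines with unrelated changes would share. Across genes, which are not independent replicates, the changes of the 2 lines correlated at 0.738, against a simulated 0.503, with a covariance of 0.272 against 0.00944, a difference of 0.262. They had the same sign for 80.7% of genes (66.8% simulated). Part of the excess may come from the shared controls, which were not split between the lines. Simulated noise with those controls gave a covariance of 0.0106 at most. The correlation was 0.84 with normexp background correction, 0.834 with only probes well above background on all arrays, and 0.674 without the filter on dim probes. It was 0.705 without PHF19L sh1 replicate 1, 0.679 without PHF19L sh1 replicate 2 and 0.707 without PHF19S sh1 replicate 2. The count of genes changed the same way, 7272 in all, was 4573 without vector replicate 1 and 4502 without vector replicate 2. The largest changes in both lines were those of DDIT3, SPX, HOXD9, IL21R, KRT86 and SLC2A3. Of these DDIT3 did not differ between the lines past the threshold (−0.29, adjusted p = 0.057), and IL21R (0.44, adjusted p = 0.025) and SLC2A3 (0.29, adjusted p = 0.028) were higher in PHF19S sh1. In opposite directions, the epididymal protein gene EDDM3A changed by 1.0 in PHF19L sh1 (SE 0.13) and was at least 3.1-fold lower in PHF19S sh1, but with normexp its change in PHF19L sh1 was −0.14 (adjusted p = 0.522). DGKB also moved in opposite directions, and it too turned in PHF19L sh1 with normexp (−0.67). The 4 further genes taken by the rule for opposite directions each lost a call when a single array was left out.

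**Figure D4:**
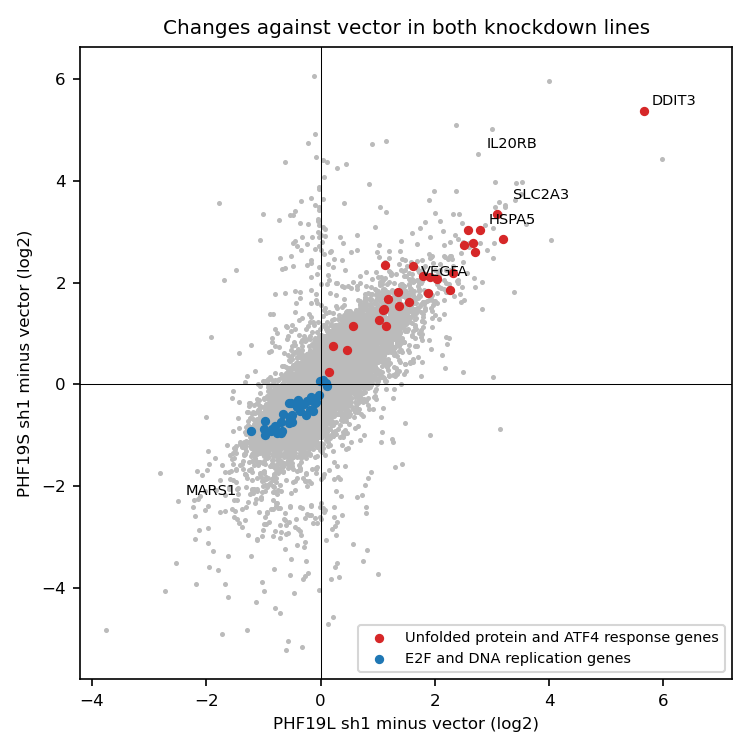
Log2 change against vector of each of 20218 genes in PHF19L sh1 (horizontal axis) and PHF19S sh1 (vertical axis), a point per gene, with unfolded protein and ATF4 response genes in red and E2F and DNA replication genes in blue. The changes correlated at 0.738, against 0.503 for simulated noise without changed genes and with a shared control group.

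The direct comparison of the knockdown lines asks where the effects of the 2 shRNAs differed. Mitosis genes were lower in PHF19S sh1 than in PHF19L sh1, with 0 of 37 higher and 19 lower (0 and 22 adjusted over the list alone, median −0.30). CENPE differed by −1.37 (SE 0.06), ASPM by −0.91 (SE 0.07), HMMR by −0.89 (SE 0.07) and ECT2 by −0.65 (SE 0.07). The list had adjusted p = 3.83e-07 (adjusted p = 0.32 with an estimated correlation). Unfolded protein and ATF4 response genes were further up in PHF19S sh1, with 13 of 28 higher and 2 lower (13 and 3 adjusted over the list alone, median 0.22). These included the phosphatase regulator PPP1R15A (1.23, SE 0.09) and the biosynthetic enzyme gene PHGDH (0.54, SE 0.07). This gave adjusted p = 0.00729 (adjusted p = 0.32 with an estimated correlation). For p53 target genes 10 of 30 were higher and 2 lower (13 and 2 adjusted over the list alone, median 0.21). TNFRSF10C was at 0.79 (SE 0.08) and SESN1 at 0.75 (SE 0.08, not called with normexp, adjusted p = 0.051). For the list camera gave adjusted p = 0.0087 (adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis genes were lower, 11 of 24 against 1 higher (11 and 3 adjusted over the list alone, median −0.22). HMGCS1 was at −0.83 (SE 0.08) and IDI1 at −0.79 (SE 0.09). Camera gave adjusted p = 0.0087 (adjusted p = 0.42 with an estimated correlation), or adjusted p = 0.0588 with normexp background correction. Heat shock genes had 7 of 15 lower and 0 higher (7 and 1 adjusted over the list alone, median −0.25). HSP90AA1 was at −0.66 (SE 0.06) and HSPE1 at −0.78 (SE 0.08). The test gave adjusted p = 0.0158 (adjusted p = 0.32 with an estimated correlation).

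Hypoxia-induced genes had 8 of 21 higher and 0 lower in PHF19S sh1 than in PHF19L sh1 (10 and 0 adjusted over the list alone, median 0.25, adjusted p = 0.0114, and adjusted p = 0.32 with an estimated correlation). Epithelial adhesion genes had 7 of 24 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.0158, and adjusted p = 0.47 with an estimated correlation), with CDH1 at 0.73 (SE 0.06). That list was not called without PHF19S sh1 replicate 2 (adjusted p = 0.0561). Ribosomal protein genes had 6 of 49 higher and 0 lower (0 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.0259, and adjusted p = 0.44 with an estimated correlation). They were not called without PHF19L sh1 replicate 2 (adjusted p = 0.165), PHF19S sh1 replicate 1 (0.0631) or PHF19S sh1 replicate 2 (0.0662), nor with quantile normalization (0.496). Respiratory chain genes had 7 of 35 lower and 0 higher (7 and 0 adjusted over the list alone, median −0.08, adjusted p = 0.0328, and adjusted p = 0.47 with an estimated correlation). They were not called without PHF19L sh1 replicate 2 (adjusted p = 0.096) or PHF19S sh1 replicate 2 (0.0561), nor with normexp (0.0816).

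The largest differences between the lines were of genes not well above background in 1 of them. P2RY12 was at least 9.9-fold, AQP4 at least 4.3-fold, XKR6 at least 4.0-fold, CPNE4 at least 4.1-fold and SCN1A at least 4.5-fold higher in PHF19S sh1. In the other direction KLF17 was at least 9.9-fold, EDDM3A at least 6.3-fold, ANGPTL8 at least 5.3-fold, VXN at least 7.5-fold, NPTX2 at least 4.1-fold and SLC6A14 at least 3.1-fold lower. All of these but SCN1A lay 8-fold or more from both other groups on the PHF19S sh1 arrays alone and had 0 other tested probes, so an artefact of that slide was not excluded for them. With normexp background correction AQP4 (adjusted p = 0.0791), XKR6 (0.211), CPNE4 (0.21), SCN1A (0.139) and SLC6A14 (0.0513) were not called. The 5 further genes taken by the rule here each lost their call when a single array was left out. Among genes measured in both lines, chosen after the values were seen, MROH7 was higher by 2.22 (SE 0.09) and IL20RB by 1.77 (SE 0.07). The vitamin D hydroxylase gene CYP24A1 differed by −1.70 (SE 0.07), the ubiquitin hydrolase gene UCHL1 by −1.55 (SE 0.11) and the cystathionine synthase gene CBS by −1.33 (SE 0.10).

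Between the lines 4892 of 20218 genes (24.2%) differed, 2298 higher and 2594 lower in PHF19S sh1, 210 and 293 of them at least 2-fold, with groups that did not overlap for 66.8% of genes (33.3% by chance). Of genes that changed the same way in both lines and differed between them, 1284 had the larger change in PHF19S sh1 and 434 in PHF19L sh1. This comparison lies between slides as well as lines, and its count was the least stable. It was 2736 without vector replicate 1, 2679 without vector replicate 2, 1479 without PHF19L sh1 replicate 1, 2623 without PHF19L sh1 replicate 2, 2010 without PHF19S sh1 replicate 1 and 1912 without PHF19S sh1 replicate 2. It was 1073 with normexp background correction and 1613 without the filter on dim probes.

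Fry passed some lists that camera did not call between the knockdown lines, for example mesenchymal transition (adjusted p = 0.0027) and TGF-beta target genes (0.003). It did not pass others, for example PRC2 subunits (0.095) and HOX genes (0.14). Lists not called by camera between the knockdown lines are given as members higher and lower in PHF19S sh1. They were 1 and 8 of 18 TGF-beta target genes (median −0.17, adjusted p = 0.0516), 6 and 12 of 28 interferon-stimulated genes (median −0.21, adjusted p = 0.148) and 3 and 10 of 32 MAPK and immediate-early genes (median 0.03, mean −0.14 and test downward, adjusted p = 0.472). Of the last EGR3 differed by −1.32 (SE 0.09). For 39 E2F and DNA replication genes they were 0 and 3 (median −0.09, adjusted p = 0.116) and for 18 NF-kB and inflammatory genes 3 and 2 (median 0.06, mean −0.02 and test upward, adjusted p = 0.979). The Polycomb lists gave 0 and 0 of 11 PRC2 subunits (median −0.07, adjusted p = 0.626), 4 and 2 of 17 PRC1 subunits (median 0.09, adjusted p = 0.71) and 3 and 3 of 30 HOX genes (median −0.05, adjusted p = 0.71). Developmental regulators bound by Polycomb gave 8 and 6 of 62 (median 0.01, but −0.02 with normexp, adjusted p = 0.71), and CDK inhibitors 2 and 0 of 7 (median 0.05, adjusted p = 0.463). Wnt and beta-catenin target genes gave 3 and 4 of 19 (median −0.02, adjusted p = 0.71), intestinal differentiation genes 1 and 2 of 12 (median −0.01 and test upward, adjusted p = 0.962), and mesenchymal transition genes 2 and 4 of 17 (median −0.14, but 0.01 with normexp, adjusted p = 0.61). Matrix-degrading protease genes gave 6 and 3 of 14 (median 0.11, adjusted p = 0.657), glycolysis genes 0 and 2 of 18 (median 0.00, adjusted p = 0.706), NRF2 antioxidant genes 4 and 1 of 20 (median −0.08, but 0.04 with normexp, adjusted p = 0.749) and cancer-testis genes 1 and 0 of 14 (median −0.10, mean 0.03 and test downward, adjusted p = 0.657). Reference genes gave 1 and 1 of 15 (median −0.04, adjusted p = 0.71), fibroblast markers 1 and 1 of 2 (median −0.02, adjusted p = 0.973) and leukocyte markers 1 and 2 of 10 (median 0.04, but −0.05 with normexp, test downward, adjusted p = 0.979). Endothelial markers gave 1 and 0 of 4 (median 0.21, adjusted p = 0.706) and markers of the HEK293 type of packaging cell 0 and 0 of 6 (median 0.15, adjusted p = 0.71). Normexp also turned the medians of MAPK (−0.09) and glycolysis genes (−0.11), and quantile normalization that of MAPK genes (−0.02).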

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

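The knockdown lines differed from each other in results that the series treats as effects of 2 isoforms. PHF19S sh1 minus PHF19L sh1 was 0.84 on the PHF19 variant 1 probe and −0.37 on the variant 2 probe, 4892 genes differed, and 143 genes were called in opposite directions against vector. Median differences of the called lists were −0.30 for mitosis genes, 0.22 for unfolded protein and ATF4 response genes, 0.21 for p53 target genes, 0.25 for hypoxia-induced genes, 0.17 for epithelial adhesion genes, 0.10 for ribosomal protein genes, −0.22 for cholesterol synthesis genes, −0.25 for heat shock genes and −0.08 for respiratory chain genes. With an estimated correlation 0 of these lists passed (smallest adjusted p = 0.32). Knockdown of different isoforms could give such differences, and so could the slide, which cannot be told apart from the PHF19S sh1 group.

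Both tests of the first pattern were written before their results were seen, and a comparison with vector was chosen after. On 69 probes the PHF19S sh1 arrays lay 8-fold or more from both other groups, with 0 of these probes well above background on all 6 arrays and 35 not measured in either other group. Only 8 of the 69 genes had other probes. Of these 14 probes 0% moved the same way by at least 1 on the log2 scale. The 95% interval was 0 to 23.2%, taking the probes as independent, and 2.78% of all tested probes moved that far either way. By any amount 10 of the 14 moved the same way, with a median of 0.11. For those 8 genes such small shifts are what a spot or printing artefact of that slide predicts. The other genes stay open. Vector differed from both knockdown lines in the same manner on 21 probes. Of the 9 other probes of their genes 7 (77.8%, 95% interval 40 to 97.2%) moved the same way by at least 1. These 9 could include others of the 21 probes themselves, whereas the count for PHF19S sh1 left out all pattern probes. The 69 probes there were of 69 genes, so that count had no such probes to leave out. But 11 of the 21 were well above background on all arrays, so this set is brighter and not a matched comparison. The pattern's spots formed 3 neighbouring pairs against a random median of 1 (0 to 4, permutation p = 0.123), which is on the side a local blemish predicts, so the bound set beforehand was too loose to exclude it and a blemish stays open.

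For the fall of MARS1 beside the rise of DDIT3, the first 2 tests were written before and the last was chosen after the result was seen. Other aminoacyl-tRNA synthetase genes had a median change of 0.50 in PHF19L sh1 and 0.49 in PHF19S sh1, which argues against a shared fall of this group. The neighbouring genes' median lay at the 48.9th percentile of windows across the genome in PHF19L sh1, which argues against a change of the whole neighbourhood. The MARS1 probe that fell ends on chromosome 12 (hg19) at 57910432, and the DDIT3 probe starts at 57911200. These are positions of probes, not of the ends of the genes. A second MARS1 probe, dimmer in vector (−0.11 against 3.51), changed by −0.14 in PHF19L sh1 and 0.01 in PHF19S sh1. A fall of the whole MARS1 transcript was therefore not shown. With a single probe falling, a change at the end of MARS1 near the DDIT3 probe cannot be told apart from a fault of that probe. Effects of DDIT3 transcription on that end were not tested.

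All tests of the third pattern, the rise of unfolded protein and ATF4 response genes in both knockdown lines, were chosen after the result was seen. Chaperone and degradation genes of the endoplasmic reticulum rose by a median of 1.71 in PHF19L sh1 and 1.98 in PHF19S sh1. These 12 genes, all called higher in each line, belong to the list whose rise was to be explained. Their rise was therefore largely fixed beforehand. It shows only that the rise of the list was not confined to its ATF4 targets. Interferon-stimulated genes lay below the stress genes by 1.41 (difference −1.41) in PHF19L sh1 and 1.60 in PHF19S sh1. The stress list was taken up because it was the most shifted, so any other list would lie below it. Interferon-stimulated genes were themselves called higher in both lines at the preset correlation (medians 0.30 and 0.36). The difference therefore cannot decide whether an interferon response to the hairpin RNA took part. With 1 control line in the series, a change of the vector cells rather than of both knockdown lines stays open. An effect of lower PHF19 on the stress response also stays open and was not tested.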

How the results depend on the processing

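With normexp background correction the numbers changed against vector stayed within 1.5 times of the main ones (9032 for PHF19L sh1 and 11077 for PHF19S sh1), but 1073 genes instead of 4892 differed between the knockdown lines, and the correlation of the 2 lines' changes was 0.84 instead of 0.738. The PHF19 variant 2 probe in PHF19L sh1 was 0.07 (adjusted p = 0.717), and the test of mitosis genes in PHF19L sh1 changed direction at a median of −0.14. In PHF19L sh1 OPN1SW (−0.27), EDDM3A (−0.14), DGKB (−0.67) and CXCL8 (−0.54) reversed. In PHF19S sh1 AQP4 (−0.1), SCN1A (−0.19), ALOX12 (−0.58), SCN4A (−0.23), CXCL8 (−0.46) and BARX1 (−0.5) reversed. The background model and the offset of 50 were changed together. The same 50 was added on every array before scaling by its 75th percentile. That percentile of processed signal was lower on the vector arrays (424.6 and 486.9) than on the knockdown arrays (570.5 to 653.9). The step can thus by itself move dim genes downward against vector, so their reversal does not decide whether they rose. How much it moved each gene was not tested.

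Without the filter on dim probes 1613 genes differed between the knockdown lines, the correlation was 0.674, and the PHF19 variant 2 difference between the lines, −0.37, had adjusted p = 0.0771. The correlation was 0.834 with only probes well above background on all arrays and 0.789 with only the groups compared. KRT80, whose probes moved in opposite directions, was −0.85 in PHF19L sh1 and −1.04 in PHF19S sh1 with only the groups compared instead of 3.12 and 3.58, because another of its probes was then the brightest. Of 6085 genes with several tested probes, 271 in PHF19L sh1 and 412 in PHF19S sh1 had probes called in both directions against vector. Between the lines 53 did. The direction of such a gene is that of its brightest probe. The 2-fold threshold left 1127 genes for PHF19L sh1, 1987 for PHF19S sh1, 503 between the lines and 791 shared by both lines. With an estimated correlation 0, 0 and 0 gene lists were called in the 3 comparisons, against 11, 12 and 9. The estimate was −0.004 for the unfolded protein list, below the preset 0.01, and 0.109 for epithelial adhesion genes. In the simulation of independent genes the shifted list went from adjusted p = 2.8e-24 to 0.047 in PHF19L sh1. Where the estimate lay below the preset value, a lost call therefore does not show that correlated members produced the shift.

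Each array was left out in turn, and a lone sample is then assumed to vary like the other groups. Genes changed in PHF19L sh1 numbered 5838 to 9006, those between the knockdown lines 1479 to 2736 and the shared calls 4502 to 6222, and the correlation was 0.679 to 0.76. The PHF19 variant 2 probe was −0.14 to 0.01 in PHF19L sh1 and −0.36 to −0.39 between the lines. KRT80 was −0.85 to 3.24 in PHF19L sh1 and −1.04 to 3.6 in PHF19S sh1. Fewer arrays lower the power of each test, and what else moved the counts was not tested.

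Quantile normalization, the percentile over probes above background, the authors' value table, kept outlier spots and the trended prior kept the counts of genes, gene lists and shared calls within 1.5 times. The mean of a gene's probes did so for genes and shared calls, and every probe on its own for genes, with the other counts not run. Fitting the replicate number as a block gave 8566, 10693 and 3574 genes, and deviations of equally numbered replicates correlated at −0.108, 0 and −0.039, so the replicate block was not used. Crossed pairing of the replicates, chosen after the data were seen, gave 9003 genes for PHF19L sh1. Among genes well above background on all 4 arrays compared, a limit also chosen after, 8934, 10353 and 4338 were called. A slide block could be fitted only for PHF19L sh1 against vector, where it changes nothing by construction, and it was not run for the comparisons of PHF19S sh1, which lie between slides.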

Other observations

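In each knockdown line 1 of the 2 PHF19 transcript probes was lower than in vector, at 50% in PHF19L sh1 and 73.7% in PHF19S sh1. The PHF19S sh1 value lies between slides, so the slide and the shRNA cannot be told apart for it. The changes of the 2 lines correlated at 0.738, against 0.503 for simulated noise with a shared control group. A hypothesis is that both lines entered an endoplasmic reticulum stress state with slower replication. Rescue with shRNA-resistant PHF19 and a second shRNA per isoform could test whether the changes come from PHF19. They would not test the stress state or the speed of replication, which were not measured here.

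Among developmental regulators bound by Polycomb, 29 fell and 2 rose in PHF19L sh1, and 34 fell and 6 rose in PHF19S sh1. The list did not pass camera with an estimated correlation (adjusted p = 0.14 and 0.19). Release of Polycomb targets from repression would raise genes that were repressed in vector. The measured members did not show more increases than decreases. Most of them were already well above background on both vector arrays, so their repression there was not shown. Listed genes not well above background on both arrays of any line were not tested. These counts therefore cannot decide whether repressed targets were released. Array intensities do not show where Polycomb complexes bind.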
